A study of Gallus gallus and Dromaius novaehollandiae with 40 samples.

How the data were processed

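RNA was sequenced from limb-forming tissues of chick (Gallus gallus) and emu (Dromaius novaehollandiae) embryos. Stages are Hamburger and Hamilton (HH) stages, the standard series for the chick. The labels describe 40 libraries, and counts of 35 of them were analysed; the other 5 are emu HH18 libraries, which are not analysed here. Counts came as 4 tables of whole numbers per gene. The first holds chick forelimb, hindlimb and flank at HH18 (4 libraries each), and the next the same tissues of the emu (2 libraries each, numbered 583 and 595). Both other tables hold early tissue from the level of the forelimb: lateral plate mesoderm, somatopleure and splanchnopleure of the chick (3 libraries each) and of the emu (3, 3 and 2). The somatopleure holds the outer layer into which the lateral plate splits, and the limb bud grows from it. The splanchnopleure holds the inner layer, on the side of the gut.

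Per the labels, lateral plate was taken at HH10 and the split layers at HH13, except that emu lateral plate 1 is labelled HH13 and emu somatopleure 13 is labelled HH10. Apart from those libraries, tissue and stage change together, so an early comparison with the lateral plate is also one between stages. Groups followed the tissue in the labels. The HH18 and early libraries were made with different RNA isolation and library kits, so no value was compared across these stages. The labels do not say whether libraries of one tissue came from separate embryos. The p-values therefore measure the spread between these samples, which may be technical.

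The deposited values are read counts per gene, not normalized. The submitters' processing notes name STAR, featureCounts, DESeq and the chicken assembly galGal4 for the libraries of both species, without versions. Which genome the emu reads were aligned to, and how reads shared by near-identical or overlapping genes were counted, is not given in the sources used here, so counts of such genes are uncertain. The early tables of both species list the same 12338 gene symbols, of which 10037 are current symbols and 367 older ones in the RefSeq gene table used for names; 1383 are LOC identifiers. The HH18 tables name genes by numbered identifiers, and 0 of them matched that gene table. HH18 genes are therefore given by identifier, at most 2 per direction, and neither gene lists nor species differences could be computed at HH18.

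Total counts per library ran from 13616330 to 74373484 in the chick HH18 table, 9798323 to 22779188 in the emu HH18 table, 5061393 to 8348865 in the chick early table and 7350786 to 8601471 in the emu early table. The chick HH18 table has 1 row with no identifier, which held 0.103% to 0.305% of a library and was left out of library sizes and tests. No pair of replicates differed by as little as sampling noise (lowest chi-square per degree of freedom, 4.04), so none was treated as a repeat of the same library. The biological coefficient of variation was 0.225 for chick HH18, 0.181 for emu HH18, 0.168 for the chick early table and 0.221 for the emu early table.

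Each table was fitted as a whole with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F test, two-sided, Benjamini-Hochberg adjustment over all genes tested). Genes with an adjusted p under 0.05 are said to have risen or fallen in the first tissue named. All adjusted p-values in the text are edgeR's unless another tool is named. Fold changes are log2 values, with their standard error (SE), and levels are in CPM (counts scaled to a common library size by TMM), as mean ± SD over libraries. A gene with no count in any library of a tissue is given as a lower bound against a floor of 3 counts per library. With 1 to 3 counts over a tissue's libraries the ratio is given with an exact 95% Clopper-Pearson interval. Floors and intervals cover counting error only.

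For the early stages, a species difference is the log2 fold change in the chick minus that in the emu, tested as an interaction in a single edgeR fit over both species (9736 genes). A difference in level between species, which also carries gene length and annotation, enters no test. Of 24 gene lists, 21 had at least 4 measured members in a comparison and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Lists of anterior Hox, posterior Hox and red blood cell genes had too few measured members. In all, 276 of the 402 list genes are in the early tables. A count "adjusted over the list alone" repeats the adjustment within a list's members. No list call held when camera estimated the correlation, and that p is given beside each call.

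Genes are named by a rule: the 5 largest rises and 5 largest falls with a symbol, a mean log2 CPM of at least 1 and no overlap between the libraries of the tissues; 23 key genes of early limb and lateral plate development, of which 17 are in the tables, whatever their result; and up to 4 members of each list with the smallest p. Of the key genes, NKX2-5 was too low to be tested in either species. For species differences the rule takes the largest differences in each direction, the key genes and the list members in the same way. Some genes that the rule names are not reported here. The groups, tests, lists, this rule and most alternatives were fixed before the data were examined.

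The chick HH18 labels number the libraries 1 to 4 in each tissue. Deviations from the tissue means correlated at 0.569 to 0.783 for the 12 pairs of libraries with the same number, at 0.196 to 0.500 between numbers 1 and 2 or 3 and 4, and at -0.612 to -0.433 otherwise, so the numbers pair the libraries across tissues. The emu HH18 labels share the numbers 583 and 595 across tissues. The 6 pairs of emu libraries with the same number correlated at 0.242 to 0.378 and the others at -0.378 to -0.242. With 2 libraries per tissue the deviations mirror each other, so these are 3 separate values, and they pair the emu libraries less firmly. The fit with the number as a block is given beside the HH18 counts. The alternatives tried were DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, only the compared tissues in the fit, the replicate block, each library left out in turn and the emu fits without both libraries of another stage label.

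The tests were tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold among the real genes. For early somatopleure against lateral plate, edgeR recovered 59 and 92 of them at the chick's depth and spread (10071 genes) and 44 and 84 at the emu's (10640 genes). For forelimb against flank at HH18 it recovered 65 and 91 in the chick (13768 genes) and 44 and 83 in the emu (13970 genes). DESeq2 recovered as many genes or more, but made more false calls in every comparison. In the emu it made 35 against edgeR's 8 for early somatopleure against lateral plate, and 41 against 17 for forelimb against flank. For the species difference of somatopleure against lateral plate it made 35 against 12. Genes called by DESeq2 alone are therefore less certain.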

Results

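Emu wings stay small and start to grow late, while chick wings and the legs of both birds do not. The series compares gene expression in the limb-forming tissues of both species. At HH18, when chick limb buds have begun to grow, forelimb, hindlimb and the flank between them were sequenced in the chick (4 libraries per tissue, 13616330 to 74373484 counts) and in the emu (2 libraries per tissue, 9798323 to 22779188 counts). Earlier tissue at the level of the forelimb was sequenced as lateral plate mesoderm and, after the lateral plate has split, as somatopleure and splanchnopleure. The chick has 3 early libraries per tissue (5061393 to 8348865 counts), and the emu has 3, 3 and 2 (7350786 to 8601471 counts).

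At HH18 the question is how far each limb field differs from the flank, which forms no limb, and how the forelimb differs from the hindlimb. In the chick, both limb buds stood far from the flank. On the first principal component (38.8% of the variance) the flank libraries lay between 48.1 and 70.4 and all limb libraries between -42.7 and -14.8. Against the flank, 4146 of 13768 genes changed in the forelimb (2018 rose, 2128 fell) and 4933 in the hindlimb (2369 rose, 2564 fell). Between forelimb and hindlimb 820 genes differed, 540 higher and 280 lower in the forelimb. With the library number as a block, these counts were 7709, 8205 and 2149.

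The HH18 tables carry no gene names, so these changes can only be given by identifier. In the chick forelimb, gene9452 stood at 12.2 ± 1.31 CPM (SD, n = 4) against no count in the flank, at least 101-fold higher. The gene13236 fell by 5.38 on the log2 scale, from 63.5 ± 8.39 in the flank to 1.54 (SE 0.30, adjusted p = 1.36e-07). In the hindlimb, gene9968 stood at 34.6 ± 3.81 CPM, at least 286-fold above the flank, and gene9452 at 23.1 ± 5.13, at least 191-fold above it. The gene795 fell by 4.95 in the hindlimb (SE 0.27, adjusted p = 8.84e-08). Between the limbs, gene14257 was higher in the forelimb (153 ± 32.7 against 2.92 CPM; log2 fold change 5.71, SE 0.22, adjusted p = 2.10e-08), and so was gene798 (12.4 ± 2.74 against 0.193; 5.97, SE 0.46, adjusted p = 6.40e-06). Higher in the hindlimb was gene21202, which had no count in the forelimb (at least 93.7-fold).

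**Figure D1:**
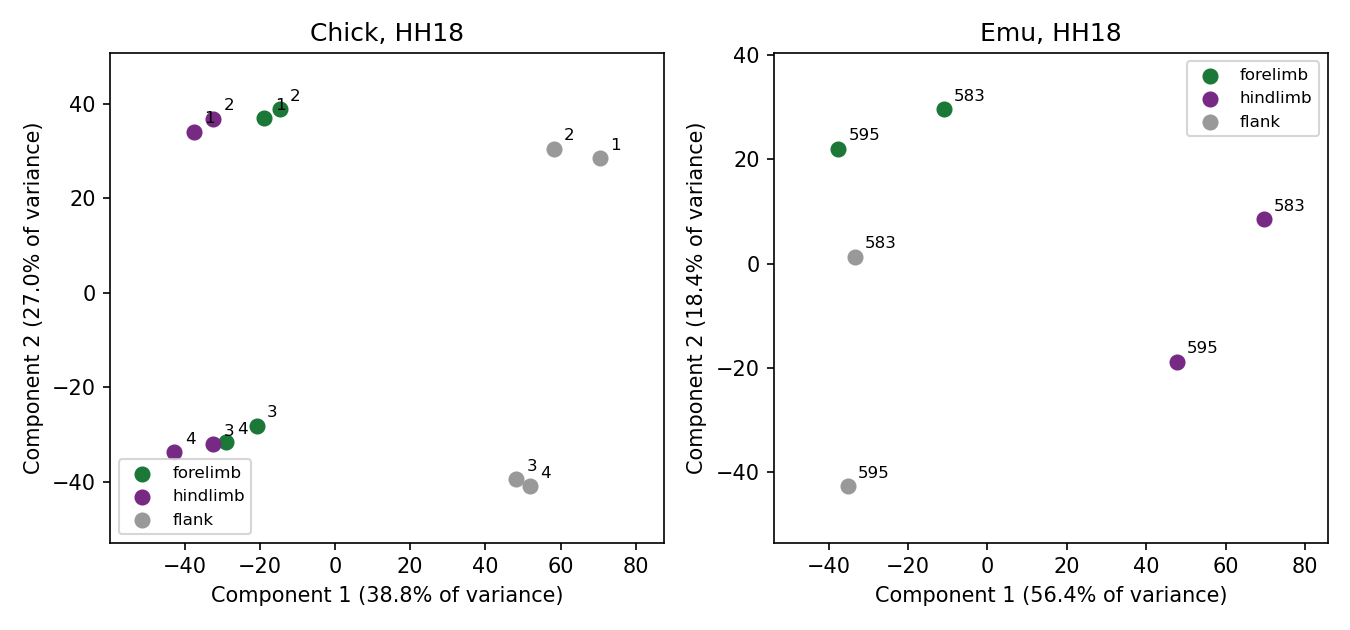
Scores of the HH18 libraries on the first and second principal components of log2 CPM, chick (left, 12 libraries) and emu (right, 6 libraries), with each point labelled by its replicate number. In the chick the first component (38.8%) parts the flank from both limbs; in the emu it (56.4%) parts the hindlimb from the forelimb and the flank.

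In the emu at HH18 the hindlimb stood apart on the first component (56.4% of the variance), where the hindlimb libraries were at 47.7 and 69.6, the forelimb libraries at -37.6 and -11.0 and the flank libraries at -35.2 and -33.4. On the second (18.4%) the forelimb libraries were at 22.0 and 29.5 and the flank libraries at -42.6 and 1.33. Of 13970 genes, 1696 changed in the hindlimb against the flank (700 rose, 996 fell) and 1083 differed between forelimb and hindlimb (752 higher and 331 lower in the forelimb). Between forelimb and flank edgeR called 2 genes. With the library number as a block, the counts were 2915, 2188 and 41 in the same order. DNOV00013100 rose to 84.1 ± 9.24 CPM (SD, n = 2) from 11.2 ± 1.30 (log2 fold change 2.90, SE 0.20, adjusted p = 0.0244), and DNOV00002933 fell by 2.23, to 24.6 ± 3.80 from 116 ± 5.76 (SE 0.14, adjusted p = 0.0244). At an unadjusted p under 0.05 there were 884 genes, and DESeq2 called 154. With changed genes simulated, DESeq2 made 41 false calls and edgeR 17, which sets no rate here. Among the largest hindlimb changes, DNOV00002404 fell by 5.31 against the flank (0.113 against 4.56 ± 1.80 CPM; SE 0.53, adjusted p = 0.00782).

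These emu counts rest on few libraries. Neither gene called between forelimb and flank was called without forelimb 583 (adjusted p = 0.147 for DNOV00013100 and 0.119 for DNOV00002933), forelimb 595 (0.0714 for both), flank 583 (0.38) or flank 595 (0.266); 0 genes were called without forelimb 583, flank 583 or flank 595. The hindlimb count against the flank was 54 without flank 583, 237 without hindlimb 583, 344 without flank 595 and 924 without hindlimb 595; that between the limbs was 21 without forelimb 595, 150 without hindlimb 583, 372 without forelimb 583 and 578 without hindlimb 595. Chick fits on 2 numbers per tissue, as many libraries as the emu has, were added after seeing the data. They called 652 to 3428 genes between forelimb and flank, 1257 to 3990 between hindlimb and flank and 40 to 561 between the limbs. Whether the species differ at HH18 was not tested, since the identifiers of the 2 tables share no names.

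**Figure D2:**
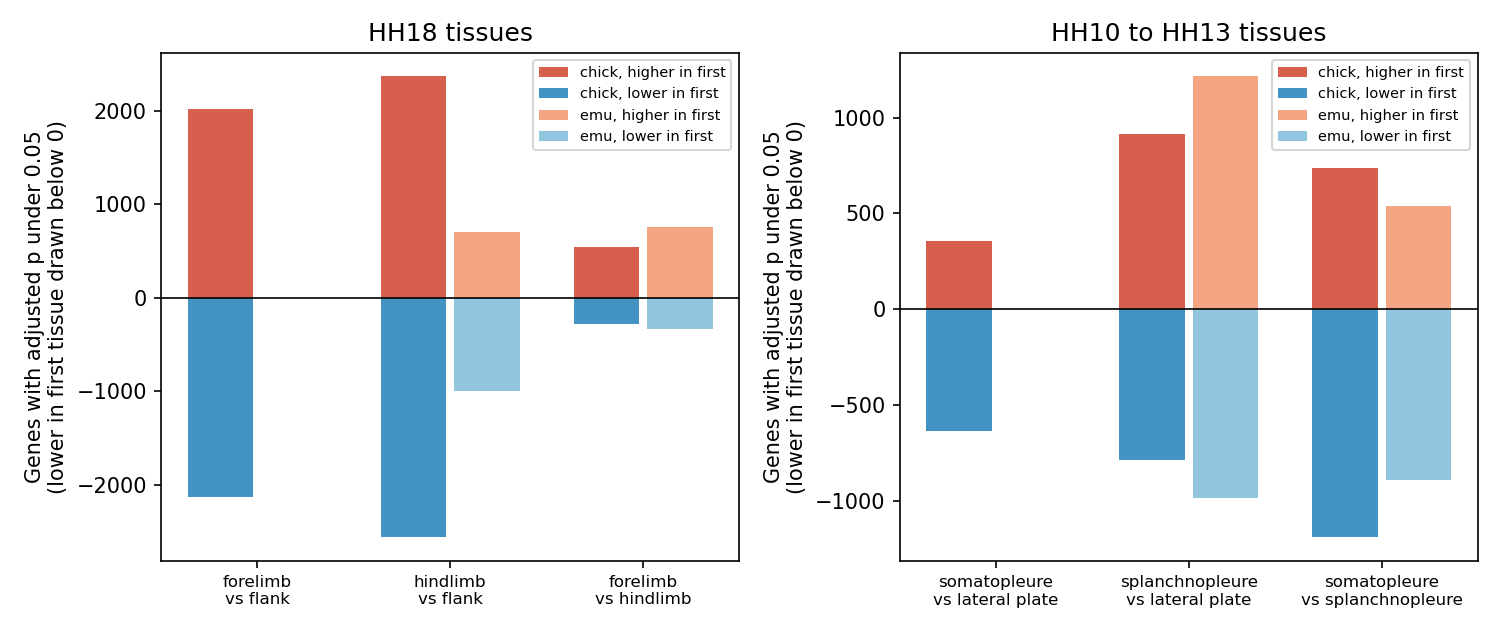
Number of genes called in each comparison (edgeR, adjusted p under 0.05), split into those higher and lower in the tissue named first. The emu bars for forelimb against flank (2 genes) and early somatopleure against lateral plate (0 genes) are close to the axis, while the matching chick bars hold 4146 and 987 genes in all.

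The early libraries ask which genes come on as the limb field forms in the somatopleure. In the chick somatopleure against the lateral plate, TBX5, the T-box gene that starts forelimb outgrowth, rose to 133 ± 8.64 CPM (SD, n = 3) from 1.82 ± 1.25, a log2 fold change of 6.25 (SE 0.69, adjusted p = 2.95e-04). ALX1, a homeobox gene of mesenchyme, rose by 6.80 (46.5 ± 13.2 against 0.395 ± 0.301 CPM; SE 0.92, adjusted p = 9.23e-04). TWIST1, a transcription factor of mesenchymal cells, rose by 4.47 (80.2 ± 33.3 against 3.72 ± 2.19; SE 0.49, adjusted p = 2.95e-04). PCDH15, a protocadherin, PRRX2, a homeobox gene of limb mesenchyme, and HS3ST6, an enzyme that modifies heparan sulfate, rose by 5.36, 4.88 and 4.84. WNT2B, a WNT ligand of the early forelimb field, rose by 3.55 (SE 0.56, adjusted p = 0.00246), and ALDH1A2, which makes retinoic acid, rose by 1.58 to 1189 ± 139 CPM (SE 0.21, adjusted p = 8.80e-04). In all, 987 of 10071 genes changed (355 rose, 632 fell).

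Among the largest falls in the chick somatopleure, SLC28A3, a nucleoside transporter gene, had no count against 5.06 ± 1.17 CPM in the lateral plate (adjusted p = 0.00275). GUCA2A, a gut peptide hormone, fell by 8.08 to 0.587 ± 0.405 CPM from 163 ± 68.1 (SE 0.49, adjusted p = 5.54e-06). APOH, a plasma protein, fell by 6.25, and DLL1, a Notch ligand of the presomitic mesoderm, by 6.77. IHH, a hedgehog ligand of endoderm, had no count in the somatopleure and was at least 7.81-fold lower. Among the remaining key genes, the level of FGF10, the FGF that mesenchyme sends to the limb ectoderm, was 20.9 ± 2.93 against 11.1 ± 5.42 CPM (0.89, SE 0.32, adjusted p = 0.113, and 0.0226 without lateral plate 30). DUSP6, an FGF target, was level at 126 ± 6.32 and 123 ± 4.37 CPM (adjusted p = 0.859). PRRX1, a homeobox gene of limb mesenchyme, rose by 1.63 (adjusted p = 0.0418), and its call was lost without lateral plate 30 (0.151), 31 (0.0855) or 32 (0.0971) or somatopleure 60 (0.104) or 63 (0.1), and by DESeq2 (0.0542). FGF8 fell, at 0.166 ± 0.191 against 4.92 ± 6.02 CPM (adjusted p = 0.0344); that call was lost without lateral plate 30 (0.141) or somatopleure 15 (0.053), 60 (0.104) or 63 (0.0991). HAND1, GATA4, GATA5, GATA6, TBX20, SNAI2 and ETV4 did not pass, though GATA5 did without lateral plate 30 (0.0478), SNAI2 without somatopleure 15 (0.00505) and ETV4 without somatopleure 63 (0.0344), and DESeq2 called GATA5 (-0.62, 0.0295) and SNAI2 (-0.54, 0.0273).

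By gene list, 5 of 16 limb mesenchyme regulators rose and 3 fell (6 and 4 adjusted over the list alone, camera adjusted p = 0.304), with MSX2 up 1.95 beside TWIST1 and ALX1, and SALL3 down (-1.01). Of 13 genes that respond to FGF and ERK signalling, none rose and 3 fell (0 and 4 adjusted over the list alone): the feedback inhibitors SPRY2 (-1.78), IL17RD (-1.38) and SPRY1 (-1.06). As a list they were lower (adjusted p = 0.0276, and adjusted p = 0.304 with an estimated correlation), a call lost without somatopleure 15 (0.0733) or 60 (0.0958). Without somatopleure 63, 6 of these genes fell; SPRY1 was lost without lateral plate 30 (0.153) or 32 (0.105) or somatopleure 60 (0.105) or 63 (0.101). FGF ligands and receptors had 1 rise and 4 falls among 12 (2 and 4 adjusted over the list alone, adjusted p = 0.448), among them the receptor-like FGFRL1 (-4.17) and FGF18 (-5.84). Without lateral plate 30, 2 of them fell, and none rose without lateral plate 32 or somatopleure 15. Of 11 hedgehog pathway genes 2 rose and 5 fell (2 and 6 adjusted over the list alone, adjusted p = 0.0994): the co-receptor BOC rose by 2.58, while SHH (-3.30) and its target PTCH1 (-2.13) fell. Of them 1 rose without lateral plate 30 or 32 or somatopleure 60 or 63, and the list passed without lateral plate 30 (0.0351). In the WNT pathway 4 of 22 rose and 3 fell (the same numbers adjusted over the list alone, adjusted p = 0.304), among them WNT5B (-2.45) and WNT11 (-2.38); the rises numbered 1 without lateral plate 30 or 32 or somatopleure 63, and 2 without lateral plate 31 or somatopleure 15 or 60. For 11 retinoic acid genes, 2 rose (4 adjusted over the list alone, adjusted p = 0.0276, and adjusted p = 0.290 with an estimated correlation), a call lost without lateral plate 30 (0.0594) or somatopleure 63 (0.0621), and 1 rose without lateral plate 32 or somatopleure 60 or 63.

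Markers of other cell types moved in the same comparison. Of 14 endothelial genes 11 fell and none rose (the same numbers adjusted over the list alone, adjusted p = 1.74e-12, and adjusted p = 0.253 with an estimated correlation), such as the endothelial cadherin CDH5 (-1.81), TIE1 (-1.79) and SOX18 (-1.94). Of 4 somite genes 3 fell (3 adjusted over the list alone, adjusted p = 0.00348, and adjusted p = 0.253 with an estimated correlation): MEOX1 (-3.27), PAX3 (-5.02) and TCF15 (-2.31). Of 7 endoderm genes 3 fell (5 adjusted over the list alone, and 5 over all genes without somatopleure 15, adjusted p = 0.00416, and adjusted p = 0.276 with an estimated correlation), including HHEX (-2.58) and FOXA2 (-3.51). Of 8 genes of the posterior growth zone, where the body axis extends, 5 fell and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.00841, and adjusted p = 0.276 with an estimated correlation), including TBX6 (-5.38) and CDX2 (-2.81). Without lateral plate 30, 3 fell, 2 rose without somatopleure 15 and none rose without lateral plate 30 or 32 or somatopleure 60 or 63. The total of changed genes was 596 without lateral plate 30 and 581 without lateral plate 32, against 987.

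In the chick splanchnopleure against the lateral plate, MAB21L1 and MAB21L2 rose by 7.23 (SE 0.98, adjusted p = 0.00137) and 5.35 (SE 0.99, adjusted p = 0.00563), COLEC10, a secreted lectin, by 5.73 and DUSP26, a phosphatase, by 5.26. The potassium channel gene KCNF1 stood at 7.26 ± 2.07 CPM with 3 counts in the lateral plate (ratio 49.3, interval 16.6 to 242). DUSP6 fell by 1.35 to 48.3 ± 6.33 from 123 ± 4.37 CPM (SE 0.11, adjusted p = 1.04e-04), ETV4, another FGF target, by 1.83 (SE 0.34, adjusted p = 0.00559), FGF10 by 1.67 (SE 0.36, adjusted p = 0.0110) and SNAI2, a repressor of epithelial genes, by 1.41. TBX6 and DLL1 fell by 5.55 and 4.86; PAX3 had 3 counts in the splanchnopleure against 8.65 ± 2.94 CPM (ratio 64.6, interval 21.7 to 316), and FGF8 none (at least 11.7-fold lower). In all 1697 genes changed (913 rose, 784 fell); without lateral plate 30 or 32 or splanchnopleure 64 there were 816, 848 and 842.

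The calls of 3 other key genes were lost with some of the libraries left out. TBX5 (2.56, adjusted p = 0.0407) was lost without lateral plate 30 (0.155), 31 (0.0555) or 32 (0.107) or splanchnopleure 50 (0.133) or 64 (0.103). HAND1 (1.35, adjusted p = 0.0293) was lost without lateral plate 30 (0.0713) or 32 (0.0946) or splanchnopleure 64 (0.121). PRRX1 (-1.76, adjusted p = 0.0248) was lost without lateral plate 31 (0.0649) or 32 (0.0886) or splanchnopleure 64 (0.0634). By list, 8 of 13 FGF and ERK response genes fell and none rose (10 adjusted over the list alone, adjusted p = 2.52e-05, and adjusted p = 0.170 with an estimated correlation), among them DUSP4 (-1.26) and IL17RD (-1.62). Limb mesenchyme regulators fell too, 6 of 16 (the same number adjusted over the list alone, adjusted p = 0.00275, and adjusted p = 0.170 with an estimated correlation), including SALL1 (-1.35), SALL3 (-1.45) and ALX4 (-2.84); 3 fell without splanchnopleure 64. Of 11 retinoic acid genes 6 rose and 1 fell (the same numbers adjusted over the list alone, adjusted p = 0.0166, and adjusted p = 0.351 with an estimated correlation), both synthesis (RDH10, 2.98) and breakdown enzymes (CYP26A1, 3.64; CYP26B1, 2.73). Of 8 posterior growth zone genes 7 fell and CYP26A1 rose (the same numbers adjusted over the list alone, adjusted p = 0.00275, and adjusted p = 0.248 with an estimated correlation), with 4 falls without lateral plate 30 or splanchnopleure 64. HHIP (3.83), a hedgehog target, was among 4 of 11 hedgehog genes that rose (4 adjusted over the list alone, adjusted p = 0.0911), 2 of which rose without lateral plate 30, and the list passed without lateral plate 32 (0.0486). Of 7 splanchnic mesoderm genes 4 rose (4 adjusted over the list alone, adjusted p = 0.00865, and adjusted p = 0.430 with an estimated correlation), 1 without lateral plate 30 and 2 without lateral plate 32 or splanchnopleure 64. Of 4 somite genes 3 fell and 1 rose (the same numbers adjusted over the list alone, adjusted p = 0.102). Of 5 nephric genes 2 fell (2 lower and 1 higher adjusted over the list alone, adjusted p = 0.102), 1 without lateral plate 31 or 32 or splanchnopleure 50 or 64. Without lateral plate 31, 1 rose, and the nephric list passed without splanchnopleure 61 (0.0134).

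Set directly against the splanchnopleure, TBX5 was higher in the chick somatopleure by 3.69 (133 ± 8.64 against 10.2 ± 8.65 CPM; SE 0.55, adjusted p = 9.93e-04), FGF10 by 2.56 (20.9 ± 2.93 against 3.54 ± 1.11; SE 0.36, adjusted p = 6.40e-04), PRRX1 by 3.39 (687 ± 175 against 65.3 ± 42.5; SE 0.48, adjusted p = 7.44e-04) and DUSP6 by 1.39 (SE 0.11, adjusted p = 1.63e-05). PRRX2 (5.66), TWIST1 (4.28), ALX1 (4.02) and ALX4 (3.93) were the other large rises that held with each library left out. WNT2B was higher by 3.71, SNAI2 by 0.86 and ALDH1A2 by 0.85; GATA4 (-1.77) was lower. GUCA2A was lower by 9.51 on the log2 scale, at 0.587 ± 0.405 CPM in the somatopleure. COLEC10, with 1 count in the somatopleure, stood at a ratio of 1264 (interval 226 to 49957) in favour of the splanchnopleure, and PLG, the plasminogen gene, was at least 17.1-fold lower.

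Of 10071 genes 1927 differed between the chick layers, 739 higher and 1188 lower in the somatopleure, and 1192 without splanchnopleure 64. Limb mesenchyme regulators were higher in 7 of 16 cases and lower in none (9 and 0 adjusted over the list alone, adjusted p = 1.40e-04, and adjusted p = 0.101 with an estimated correlation), with MSX2 up 2.59. Of 9 apical ridge genes 1 was higher (1 adjusted over the list alone, adjusted p = 0.00134, and adjusted p = 0.290 with an estimated correlation), and 7 were without splanchnopleure 61. FGF and ERK response genes were higher in 4 of 13 (4 adjusted over the list alone, adjusted p = 0.0228, and adjusted p = 0.290 with an estimated correlation): DUSP6, ETV1 (1.05), DUSP4 (0.94) and ETV4 (1.19), the last lost without somatopleure 63 (0.105), splanchnopleure 50 (0.0674) or splanchnopleure 64 (0.116). In the WNT pathway 8 of 22 were higher and 4 lower (10 and 6 adjusted over the list alone, adjusted p = 0.0669, and 0.0336, 0.0317 and 0.0483 without somatopleure 60, splanchnopleure 61 and splanchnopleure 64), with the targets NOTUM (3.06), LEF1 (1.79) and SP5 (2.68) higher. Hedgehog genes were lower in 6 of 11 and higher in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.208 with an estimated correlation), among them HHIP (-6.98) and PTCH1 (-2.21). Of 7 splanchnic mesoderm genes 4 were lower (6 adjusted over the list alone, adjusted p = 0.00134, and adjusted p = 0.290 with an estimated correlation), among them TCF21 (-5.23). Endothelial markers were lower in 11 of 14 (13 adjusted over the list alone, adjusted p = 2.94e-11, and adjusted p = 0.208 with an estimated correlation), with CDH5 at -2.26, and endoderm markers in 4 of 7 (6 adjusted over the list alone, adjusted p = 1.80e-04, and adjusted p = 0.233 with an estimated correlation), with FOXA2 at -4.25.

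In the emu, no gene passed the test between somatopleure and lateral plate. edgeR called 0 of 10640 genes, with 1107 at an unadjusted p under 0.05, and DESeq2 called 140. With changed genes simulated, DESeq2 made 35 false calls and edgeR 8, which sets no rate here. TBX5 stood at 31.6 ± 39.3 CPM (SD, n = 3; 51 to 585 counts) against 3.64 ± 3.85, a log2 fold change of 3.12 (SE 1.29, adjusted p = 0.445). FGF10 stood at 0.688 ± 0.511 against 3.45 ± 3.66 CPM (-2.30, SE 0.94, adjusted p = 0.444), PRRX1 at 143 ± 50.3 against 96.3 ± 15.1 (0.58, SE 0.53, adjusted p = 0.741), WNT2B at 3.65 ± 1.03 against 3.90 ± 0.484 (-0.10, SE 0.34, adjusted p = 0.946) and DUSP6 at 120 ± 41.4 against 139 ± 19.3 (-0.21, SE 0.24, adjusted p = 0.806). TWIST1 (2.74, adjusted p = 0.372) and ALDH1A2 (0.89; 0.526) did not pass either. Leaving out lateral plate 1 gave 1 called gene.

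Single genes did not pass in the emu somatopleure, but some lists did. The 13 FGF and ERK response genes lay lower as a list (adjusted p = 9.74e-04, and adjusted p = 0.564 with an estimated correlation), with SPRY1 at -1.59, IL17RD at -1.21 and SPRY2 at -0.93; no member passed over all genes and 1 did adjusted over the list alone. The 8 posterior growth zone genes lay lower too (adjusted p = 1.17e-04, and adjusted p = 0.564 with an estimated correlation), with TBX6 at -2.33 and SALL4 at -0.87; 4 were lower adjusted over the list alone. The 23 mesenchymal and matrix genes lay higher (adjusted p = 0.00278, and adjusted p = 0.616 with an estimated correlation; none adjusted over the list alone), a call lost without lateral plate 1 (0.0736) or somatopleure 5 (0.0569). The 16 limb mesenchyme regulators had an adjusted p of 0.939, with 1 higher and 2 lower adjusted over the list alone. Endothelial markers lay lower (adjusted p = 0.0417, and adjusted p = 0.665 with an estimated correlation; 1 higher and 1 lower adjusted over the list alone), a call lost without lateral plate 23 (0.0506) or 8 (0.125) or somatopleure 5 (0.975). No gene of 5 further lists passed over all genes, and these shifted only as lists. The list of 8 endoderm genes lay lower (1 gene adjusted over the list alone, adjusted p = 0.0215, and adjusted p = 0.564 with an estimated correlation). That call was lost without lateral plate 8 (0.174) or somatopleure 5 (0.102). The list of 5 nephric genes lay lower too (1 gene adjusted over the list alone, adjusted p = 0.0215, and adjusted p = 0.616 with an estimated correlation), but not without somatopleure 5 (0.524). So did the list of 9 surface ectoderm genes (1 gene adjusted over the list alone, adjusted p = 0.0280, and adjusted p = 0.616 with an estimated correlation), lost without lateral plate 23 (0.0757) or somatopleure 53 (0.774). The list of 16 BMP genes lay higher (1 gene adjusted over the list alone, adjusted p = 0.0444, and adjusted p = 0.616 with an estimated correlation), lost without lateral plate 1 (0.390) or somatopleure 5 (0.305). So did that of the 10 retinoic acid genes measured (2 genes adjusted over the list alone, adjusted p = 0.0444, and adjusted p = 0.616 with an estimated correlation). Its call was lost without lateral plate 1 (0.0900) or 8 (0.148) or somatopleure 13 (0.102) or 5 (0.394).

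**Figure D3:**
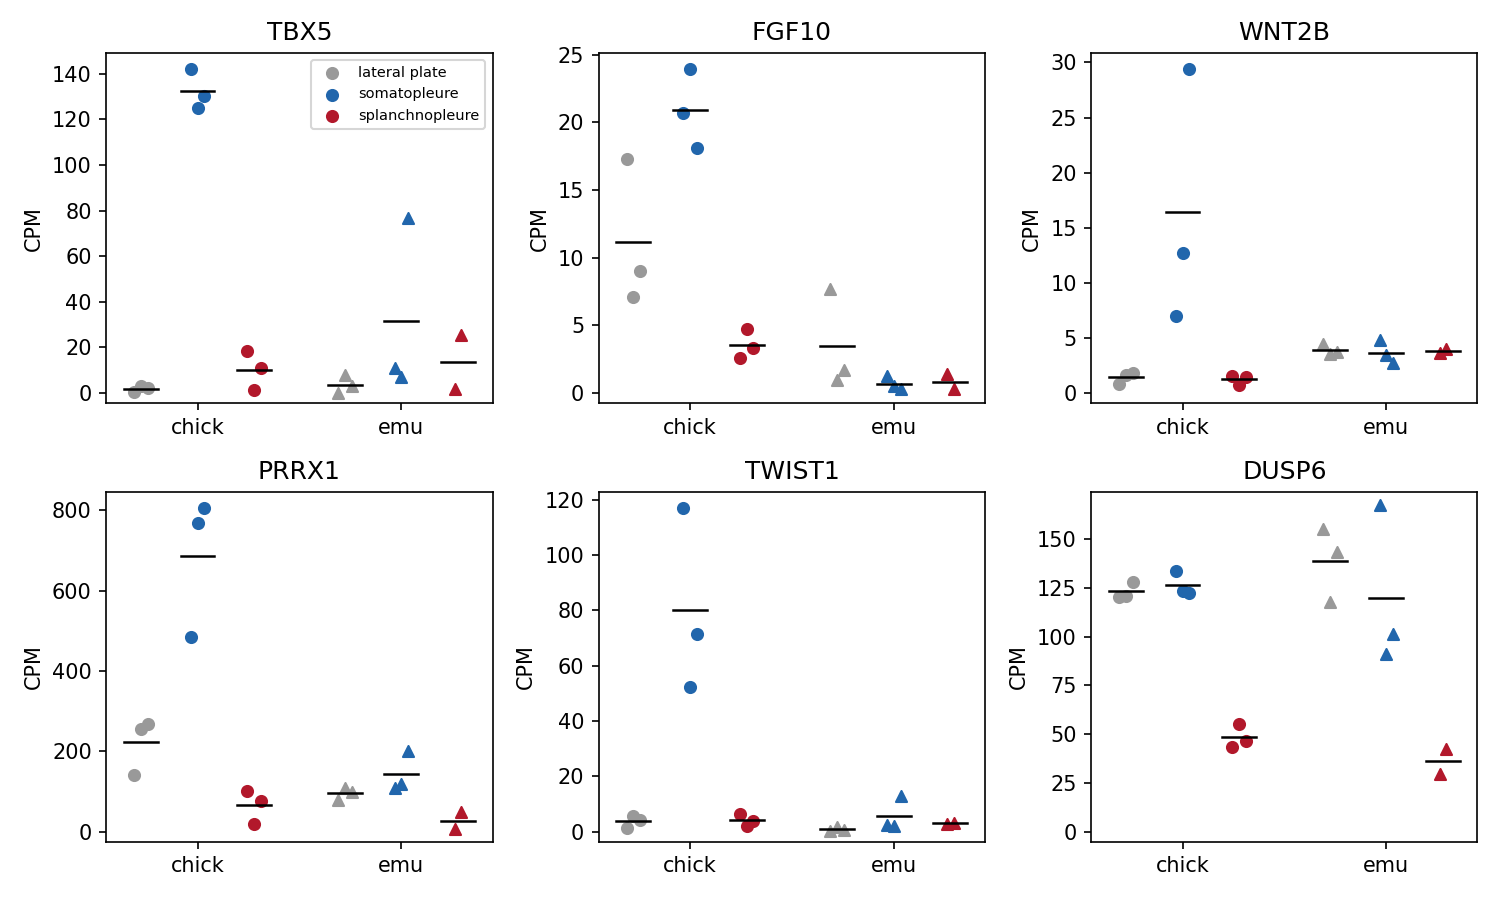
CPM of 6 key genes in each early library, with the mean of each tissue as a bar line, chick and emu side by side. TBX5 is at 133 ± 8.64 CPM in the chick somatopleure and at 31.6 ± 39.3 in the emu's, and FGF10 at 20.9 ± 2.93 and 0.688 ± 0.511; levels were not tested between species.

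The emu splanchnopleure differed from the lateral plate in 2196 of 10640 genes (1216 rose, 980 fell). COL3A1, a fibrillar collagen, rose by 7.46 to 5852 ± 4249 CPM (SD, n = 2) from 33.4 ± 30.5 (SE 1.05, adjusted p = 0.00372). COLEC10 rose by 7.51 (SE 0.93, adjusted p = 0.00280) and AQP1, a water channel, by 6.84 (SE 0.89, adjusted p = 0.00299); ANXA13, an annexin of gut epithelium, had 1 count in the lateral plate against 11.4 ± 2.77 CPM (ratio 285, interval 50.4 to 11304). TFAP2B, a regulator in ectoderm and neural crest, fell by 5.09 (SE 0.62, adjusted p = 0.00258), WNT10A by 5.14 and TP73 by 5.20. DUSP6 fell by 1.94 to 36.1 ± 9.13 from 139 ± 19.3 CPM (SE 0.29, adjusted p = 0.00456). The count of 2196 was 353 without splanchnopleure 6, 932 without lateral plate 1, 1235 without lateral plate 8 and 1433 without lateral plate 23, and 654 without both libraries of another stage label.

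HAND1, a gene of lateral mesoderm, rose by 1.73 in the emu splanchnopleure (adjusted p = 0.0285; lost without lateral plate 23, 0.0534; splanchnopleure 6, 0.167; or splanchnopleure pool, 0.0513). TBX5 (1.90, adjusted p = 0.350), FGF10 (-2.03; 0.205), PRRX1 (-1.82; 0.0784, and 0.00367 without splanchnopleure pool) and ETV4 (-1.73; 0.0631, 0.0159 without splanchnopleure pool and 0.00627 by DESeq2) did not pass. Of 23 mesenchymal and matrix genes 14 rose and 1 fell (15 and 2 adjusted over the list alone, adjusted p = 6.22e-05, and adjusted p = 0.416 with an estimated correlation), including TNC (4.47), COL1A2 (4.73), DCN (6.16) and COL1A1 (3.75); 9 rose without lateral plate 8 and 7 without splanchnopleure 6. Of 7 apical ridge genes, which also mark surface ectoderm, 5 fell (7 adjusted over the list alone, adjusted p = 6.22e-05, and adjusted p = 0.376 with an estimated correlation), BMP7 by 2.60; 3 fell without any one lateral plate library or splanchnopleure pool, and 1 without splanchnopleure 6. FGF and ERK response genes had 1 rise and 4 falls among 13 (1 and 7 adjusted over the list alone, adjusted p = 0.0539); 2 fell without lateral plate 1 or 8, and 1 without splanchnopleure 6, none rose without lateral plate 8 or either splanchnopleure library, and the list passed without lateral plate 23 (0.0323) or 8 (0.0494), splanchnopleure 6 (0.0428) or splanchnopleure pool (0.0479). Limb mesenchyme regulators fell in 6 of 16 cases (8 lower and 1 higher adjusted over the list alone, adjusted p = 0.00497, and adjusted p = 0.376 with an estimated correlation), and in 2 without splanchnopleure 6. Of 8 posterior growth zone genes 4 fell (6 lower and 1 higher adjusted over the list alone, adjusted p = 0.00253, and adjusted p = 0.416 with an estimated correlation), and 1 without splanchnopleure 6. Endothelial markers rose in 10 of 14 cases (12 adjusted over the list alone, adjusted p = 1.10e-04, and adjusted p = 0.416 with an estimated correlation), in 2 without lateral plate 1, 3 without lateral plate 23 and 0 without splanchnopleure 6.

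Between the emu layers, WNT10A was higher in the somatopleure by 4.90 (SE 0.58, adjusted p = 0.00286) and TFAP2B by 4.90 (SE 0.61, adjusted p = 0.00356). LIPC, the hepatic lipase gene, had 3 counts in the somatopleure against 66.8 ± 1.02 CPM (ratio 510, interval 174 to 2477), and ANXA13 had none (at least 28.9-fold lower). SHH (-4.32) and IHH (-4.50) were lower in the somatopleure. DUSP6 was higher by 1.73 (SE 0.29, adjusted p = 0.00789; 0.0844 without splanchnopleure 6). PRRX1 was higher by 2.39 (adjusted p = 0.0461) but not without somatopleure 13 (0.0772), 53 (0.0707) or 5 (0.0675) or splanchnopleure 6 (0.0811). TBX5 (1.22, SE 1.34, adjusted p = 0.579), FGF10 (-0.27; 0.900) and TWIST1 (0.95; 0.537) did not pass. In all 1424 genes differed (537 higher, 887 lower), 263 without splanchnopleure 6, 734 without somatopleure 13, 933 without somatopleure 53 and 453 without both libraries of another stage label.

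Limb mesenchyme regulators were higher in 5 of 16 cases in the emu somatopleure (8 adjusted over the list alone, adjusted p = 3.04e-04, and adjusted p = 0.168 with an estimated correlation), with MSX1 at 1.65 (adjusted p = 0.00993; 0.0795 without splanchnopleure 6) and LMX1B at 3.78 (adjusted p = 0.0130; 0.102 without splanchnopleure 6); 3 were higher without somatopleure 13 or 53, and 0 without splanchnopleure 6. Of 7 apical ridge genes 5 were higher (7 adjusted over the list alone, adjusted p = 8.15e-05, and adjusted p = 0.338 with an estimated correlation), BMP7 by 2.87; 1 was higher without splanchnopleure 6 and 2 without splanchnopleure pool. FGF and ERK response genes had 2 higher and 1 lower among 13 (3 and 3 adjusted over the list alone, adjusted p = 0.767), with 1 higher without somatopleure 13, 2 lower without somatopleure 53 or 5, and none of either without splanchnopleure 6. Endothelial markers were lower in 11 of 14 (12 adjusted over the list alone, adjusted p = 7.80e-07, and adjusted p = 0.535 with an estimated correlation), with LMO2 at -2.44; 6 were lower without somatopleure 13 and 1 without splanchnopleure 6. Of 23 mesenchymal and matrix genes 11 were lower and 1 higher (14 and 1 adjusted over the list alone, adjusted p = 5.79e-04, and adjusted p = 0.587 with an estimated correlation), with DCN at -4.59. Without somatopleure 13, 6 were lower, and without splanchnopleure 6, 5 were lower and none higher. Of 9 surface ectoderm genes 4 were higher (5 adjusted over the list alone, adjusted p = 0.0271, and adjusted p = 0.587 with an estimated correlation). The list call was lost without somatopleure 5 (0.122), splanchnopleure 6 (0.0591) or both libraries of another stage label (0.0615). Of them 2 were higher without splanchnopleure 6 or pool, and 1 was lower without somatopleure 5. Of 8 endoderm genes 4 were lower (7 adjusted over the list alone, adjusted p = 2.71e-04, and adjusted p = 0.231 with an estimated correlation), and 2 without somatopleure 13 or splanchnopleure 6 or pool.

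The central question of the series is whether the species differ in these changes, and the interaction tests it gene by gene. For somatopleure against lateral plate, 273 of 9736 genes differed, 88 with a higher fold change in the chick and 185 with a lower one. WNT2B rose by 3.56 in the chick and stood at -0.09 in the emu, a difference of 3.65 (SE 0.67, adjusted p = 0.0108). PCDH15 differed by 4.83 (SE 0.58, adjusted p = 0.00134): the emu lateral plate already held 45.7 ± 7.75 CPM against 1.72 ± 1.12 in the chick. CYP24A1, which breaks down vitamin D, differed by 4.93 (SE 0.78, adjusted p = 0.00388), CHRNA4, a nicotinic receptor subunit, by 5.10 (adjusted p = 0.0151), and BOC by 1.78 (adjusted p = 0.0108). In the other direction stood FGFRL1 (-4.29, adjusted p = 8.05e-04), WSCD2 (-4.91, SE 0.72, adjusted p = 0.00232), PAPPA, a protease of the insulin-like growth factor system (-5.26, SE 0.97, adjusted p = 0.0108), and RSPO3, a WNT agonist (-3.47, adjusted p = 0.0163). Without both emu libraries of another stage label, CHRNA4 (0.0557), BOC (0.0505) and RSPO3 (0.0855) did not pass.

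Apart from WNT2B, the difference did not pass for the key genes named here. TBX5 differed by 3.12 (SE 1.65, adjusted p = 0.354), TWIST1 by 1.72 (0.476), PRRX1 by 1.06 (0.519), ETV4 by 0.39 and DUSP6 by 0.25 (0.685). FGF10 differed by 3.19 (SE 0.95, adjusted p = 0.0922), with 0.0447 without emu lateral plate 23, up to 0.316 without another library, and 0.0187 by DESeq2. None of 13 FGF and ERK response genes differed, over all genes or adjusted over the list alone, and the list did not (adjusted p = 0.796); at an unadjusted p under 0.05 the whole comparison had 1667 genes, and DESeq2 called 594. Nor did any of 15 limb mesenchyme regulators (none adjusted over the list alone, adjusted p = 0.344). The list of 14 endothelial markers differed, lower in the chick change (1 gene, and 11 lower and 1 higher adjusted over the list alone, adjusted p = 6.87e-06, and adjusted p = 0.550 with an estimated correlation), with EGFL7 at -1.25 (adjusted p = 0.0506) and FLI1 at -1.73 (0.0542). Its members called lower numbered 10 without emu somatopleure 5, 2 without chick somatopleure 15 or emu lateral plate 23, and 0 without chick lateral plate 30 or 31, chick somatopleure 60 or 63, emu lateral plate 1 or 8 or emu somatopleure 13 or 53. Somite markers did likewise (1 of 4, MEOX1 at -3.22; 3 adjusted over the list alone, adjusted p = 0.00529, and adjusted p = 0.290 with an estimated correlation), with MEOX1 at 0.0505 without both emu libraries of another stage label.

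The number of differing genes was 137 without emu lateral plate 1, 144 without chick somatopleure 60 or 63, 149 without emu lateral plate 8, 160 without chick lateral plate 30, 172 without chick lateral plate 32 and 173 without chick lateral plate 31, and 88 without both emu libraries of another stage label. Regrouping the emu libraries alone gave 164 to 688 genes in 8 drawn splits, and at least 273 in 5. Chance is not excluded for this total.

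For splanchnopleure against lateral plate 924 genes differed between the species (420 higher, 504 lower in the chick). Of 23 mesenchymal and matrix genes 10 had a lower change in the chick and none a higher one (13 and 0 adjusted over the list alone, adjusted p = 7.14e-06, and adjusted p = 0.691 with an estimated correlation), among them COL1A2 (-3.54), COL5A2 (-1.95) and DCN (-3.19). ISL1, a regulator of splanchnic and limb mesoderm, rose by 2.43 in the chick and stood at -2.58 in the emu (difference 5.01, SE 0.83, adjusted p = 0.00278). TP73 differed by 5.39, CRTAC1 by 5.89, MAF by -4.91 and CRABP1, a retinoic acid binding protein, by -4.79. DUSP6 fell in both species, and its fall did not differ (0.58, adjusted p = 0.232); FGF and ERK response genes had 1 difference in each direction among 13 (the same numbers adjusted over the list alone, adjusted p = 0.576). The higher one, ETV1 (1.65, adjusted p = 0.0277), was lost without chick lateral plate 30 (0.0571), 31 (0.0503) or 32 (0.055), chick splanchnopleure 64 (0.0566), emu lateral plate 1 (0.0682) or emu splanchnopleure 6 (0.159). The lower one, SPRY2 (-1.77, adjusted p = 0.0384), was lost without chick lateral plate 30 (0.106), chick splanchnopleure 50 (0.0553), 61 (0.0697) or 64 (0.0740), emu lateral plate 23 (0.0804) or 8 (0.0687), emu splanchnopleure 6 (0.0911) or emu splanchnopleure pool (0.0892). Of the matrix genes 6 differed without chick lateral plate 31 or chick splanchnopleure 50 or 61, and 3 without emu splanchnopleure 6. Of 14 endothelial markers 4 were lower (7 adjusted over the list alone, adjusted p = 2.85e-04, and adjusted p = 0.750 with an estimated correlation). Only 1 was lower without chick lateral plate 30, 31 or 32, chick splanchnopleure 61 or emu lateral plate 1. The count was 2 without chick splanchnopleure 50 or emu lateral plate 23 or 8, 0 without emu splanchnopleure 6 and 9 without emu splanchnopleure pool. The count of all genes was 240 without emu splanchnopleure 6, 552 without emu lateral plate 1, 576 without chick lateral plate 30 and 577 without both emu libraries of another stage label.

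Between the layers 500 genes differed by species (249 higher, 251 lower in the chick), and 214 did without emu splanchnopleure 6. CYP24A1 had the largest difference, 8.71 (SE 0.80, adjusted p = 1.07e-04), with a log2 fold change of 1.45 in the chick and -7.26 in the emu. COL6A3, a collagen chain, was higher in the chick somatopleure (2.53) and lower in the emu's (-2.42), a difference of 4.95 (SE 0.81, adjusted p = 0.00287). ANXA1, an annexin, stood at 4.91 ± 2.54 against 341 ± 105 CPM in the chick layers and at 322 ± 37.6 against 452 ± 73.1 in the emu's (-5.61, SE 0.56, adjusted p = 1.45e-04). WNT2B differed by 3.79 (SE 0.70, adjusted p = 0.00639), TCF21 by -4.03 and CRABP1 by 4.47. TBX5 (2.50, adjusted p = 0.345), FGF10 (2.85; 0.181), DUSP6 (-0.32; 0.577) and TWIST1 (3.35; 0.0755, and 0.00571 without emu somatopleure 5) did not pass. Mesenchymal and matrix genes differed in 6 of 23 cases, all higher in the chick (9 adjusted over the list alone, adjusted p = 5.76e-04, and adjusted p = 0.995 with an estimated correlation), and in 2 without emu splanchnopleure 6. Of 7 apical ridge genes 1 was lower in the chick (1 adjusted over the list alone), and the list did not pass (adjusted p = 0.686).

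Across genes, the fold changes of the species were related least for somatopleure against lateral plate. Over the 9736 shared genes, Pearson's r was 0.238 (Spearman's rho 0.112) for that comparison, 0.399 (0.355) for splanchnopleure against lateral plate and 0.491 (0.384) for somatopleure against splanchnopleure; genes are not independent replicates, and no p is given. For splanchnopleure against lateral plate, 318 genes rose and 236 fell in both species, against 98.0 and 73.3 for independent lists, and 52 were called in opposite directions. Between the layers 130 and 355 were called alike, against 37.6 and 91.8, and 28 oppositely. For somatopleure against lateral plate no gene was called in the emu by edgeR; of 947 genes called in the chick, 620 (65.5%) had the same sign in the emu. The same-sign shares were 77.9% (1276 of 1638) and 81.0% (1504 of 1856) for the other comparisons.

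**Figure D4:**
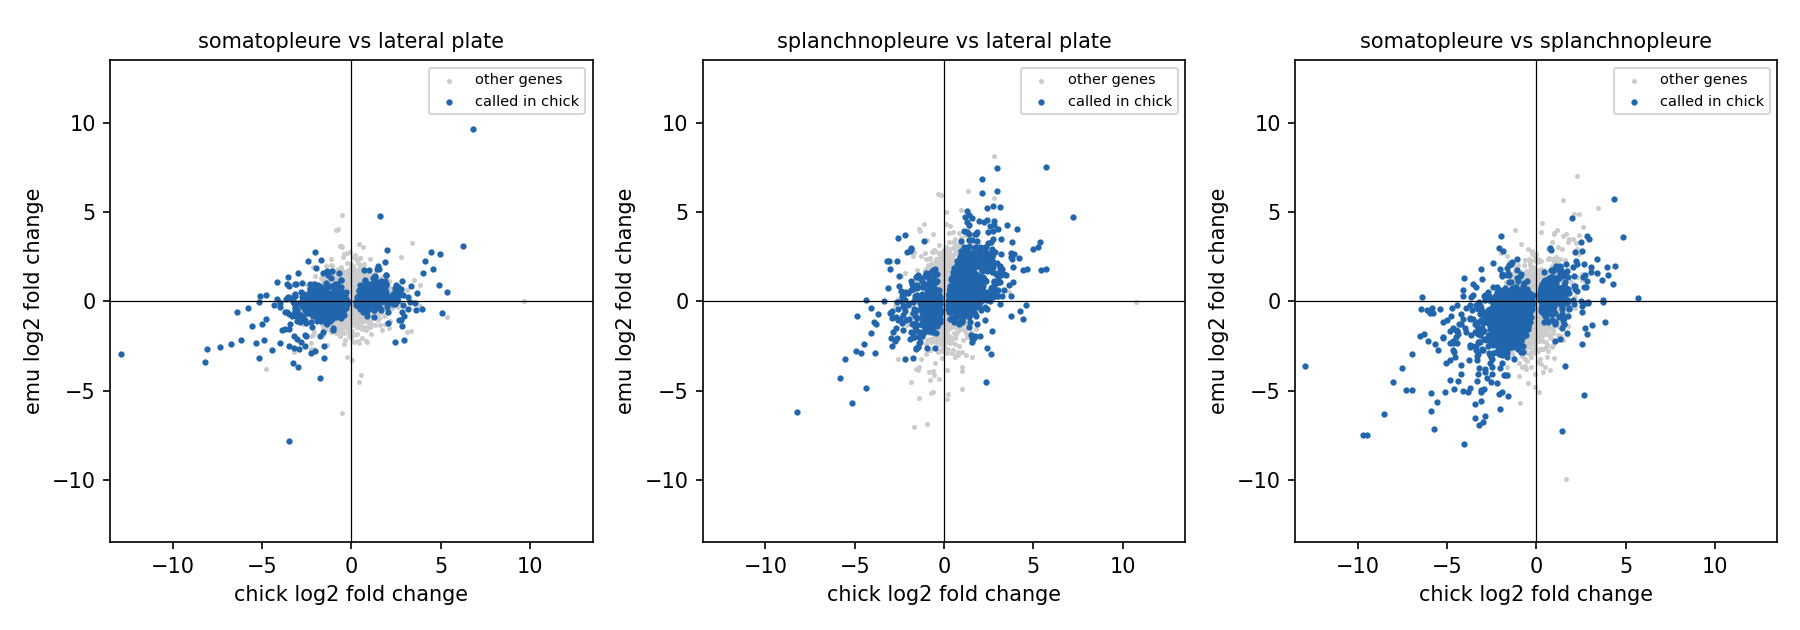
Log2 fold changes of the chick (horizontal) against the emu (vertical) for the 9736 genes tested in both species, one panel per early comparison, with the genes called in the chick marked (947, 1638 and 1856 from left to right). Pearson's r is 0.238, 0.399 and 0.491.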

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

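The tests of emu spread, stage labels, splanchnopleure cells, flank tissue and chick sequencing depth were chosen only after the results they bear on were seen.

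The early changes differed between the species in 273 genes for somatopleure against lateral plate, 924 for splanchnopleure against lateral plate and 500 for somatopleure against splanchnopleure. The first count was 137 without emu lateral plate 1, 144 without chick somatopleure 60 or 63, 149 without emu lateral plate 8, and 160, 173 and 172 without chick lateral plate 30, 31 and 32. The second was 240 without emu splanchnopleure 6, 552 without emu lateral plate 1 and 576 without chick lateral plate 30, and the last was 214 without emu splanchnopleure 6. For the first of these, the differences (log2 fold change in the chick minus that in the emu) of CHRNA4 (5.10), CYP24A1 (4.93), PCDH15 (4.83), PAPPA (-5.26), WSCD2 (-4.91) and WNT2B (3.65) passed with each single library left out, though CHRNA4 did not without both emu libraries of another stage label (adjusted p = 0.0557). IL20RA (4.09) was lost without chick lateral plate 30 (adjusted p = 0.0751) or chick somatopleure 60 (0.0553). ENPP3 (-5.13) was lost without chick lateral plate 30 (0.0505) or 31 (0.0530), chick somatopleure 60 (0.0674) or 63 (0.0633), emu lateral plate 8 (0.0600) or emu somatopleure 5 (0.0721). ASTL (5.02) was lost without chick lateral plate 30 (0.0801), 31 (0.0637) or 32 (0.0817), chick somatopleure 15 (0.0627), emu lateral plate 1 (0.0703), 23 (0.0528) or 8 (0.0521) or emu somatopleure 13 (0.0597) or 53 (0.0583). KCNS3 (-5.46) was lost without chick lateral plate 30 (0.0842), chick somatopleure 15 (0.0597), 60 (0.0987) or 63 (0.102), emu lateral plate 1 (0.0657), 23 (0.0757) or 8 (0.0770) or emu somatopleure 13 (0.0585) or 53 (0.0676). CIP1 (-4.65) was lost without chick lateral plate 30 (0.0806), 31 (0.0849) or 32 (0.0897), chick somatopleure 15 (0.0543), 60 (0.111) or 63 (0.0975), emu lateral plate 1 (0.106) or 8 (0.103) or emu somatopleure 13 (0.0944) or 53 (0.0846).

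For splanchnopleure against lateral plate the named differences were those of CHRNA4 (6.83), CRTAC1 (5.89), PTGDS (5.61), TP73 (5.39), ISL1 (5.01), GSDMA (-6.34), GRIN2A (-5.46), SLCO2B1 (-5.37), MAF (-4.91), SLC28A3 (-4.86) and SNAI2 (-1.67). Without emu splanchnopleure 6, PTGDS (adjusted p = 0.0638), SLCO2B1 (0.104) and SNAI2 (0.0611) were lost, and PTGDS also without emu splanchnopleure pool (0.0599). For somatopleure against splanchnopleure they were those of CYP24A1 (8.71), PLCL1 (5.25), GPR64 (5.03), COL6A3 (4.95), ISL1 (-6.66), CRTAC1 (-5.62), ANXA1 (-5.61), LTF (-5.49), LCAT (-5.16), WNT2B (3.79) and SNAI2 (1.60). SNAI2 was lost without emu splanchnopleure 6 (adjusted p = 0.0882). The values for PTGDS and for ISL1 between the layers rest on 1 count in a tissue and are fitted values, not bounds.

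The somatopleure of the emu differed from its lateral plate in 0 genes by edgeR (1107 at an unadjusted p under 0.05, 140 by DESeq2), and 1 without lateral plate 1, while 987 differed in the chick (596 without lateral plate 30, 581 without lateral plate 32). Over the genes called in the chick, the slope of emu on chick fold changes was 0.221, against 0.526 for splanchnopleure against lateral plate and 0.493 between the layers. A wider spread between emu libraries leaves fold changes in place. As the only cause it is argued against, since the highest slope over left-out emu libraries (0.265) lies below the lowest of the others (0.442). It may still add to the low count. The biological coefficient of variation was 0.221 in the emu and 0.168 in the chick, and edgeR recovered 44 and 59 of 100 simulated 2-fold changes. Mixed stage labels as the only cause are argued against by the slope too, at 0.272 without both libraries of another stage label. A splanchnopleure share in the emu somatopleure libraries large enough on its own to lower the slope so far is argued against by the genes it would bring. A smaller share, acting with another cause, was not tested. When chick tissue means were mixed, a splanchnopleure share of 0.5 was needed to lower the slope as far as from 0.442 to 0.265. Of 1038 genes higher in the emu splanchnopleure than in its lateral plate, with at least 10 CPM in each splanchnopleure library, 15 lay more than 10 times below what that share would bring in every somatopleure library, though 778 lay at that level or above it in at least 1. Among the 15, COL3A1 stood at 90.5 against 5852 CPM, CYP24A1 at 0.529 against 82.0 and LIPC at 3 counts against 66.8 CPM. Other causes stay open. A slower start of the emu forelimb field was not tested on its own, nor was lateral plate tissue in the somatopleure libraries. The mix of cell types in the tissues was not tested as a cause either. With the preset correlation, endothelial, somite, cell cycle and cardiac muscle lists differed between the species in this comparison, and limb mesenchyme regulators did not.

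The emu forelimb differed from the flank at HH18 in 2 genes by edgeR (884 at an unadjusted p under 0.05, 154 by DESeq2), and in 0 without forelimb 583, flank 583 or flank 595. The hindlimb differed from it in 1696 (with the numbers as a block there were 41 and 2915), with 237 without hindlimb 583, 924 without hindlimb 595, 54 without flank 583 and 344 without flank 595. Exchanged labels of forelimb and flank in 1 number would turn the differences of numbers 583 and 595 against each other, but these correlated at 0.333 across genes (0.777 for hindlimb against flank). Extra noise in forelimb or flank is argued against by the spread between numbers, at most 1.12 times the hindlimb's. Noise in every tissue was not tested. Flank tissue in the forelimb libraries could shrink the differences: the SD of the fold changes was 0.603 times that of hindlimb against flank, and 0.901 times in the chick. A forelimb close to the flank at this stage gives the same value, so these 2 cannot be told apart.

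The chick HH18 libraries part into numbers 1 and 2 against 3 and 4 on the second principal component (27.0% of the variance). Sequencing depth is argued against as the cause, since 9 of the 12 libraries have a total count inside the range of the others (16286812 to 31779990 for numbers 1 and 2, 13616330 to 74373484 for numbers 3 and 4). A batch or a difference between embryos may lie behind it, and the labels used here name neither, so no biological explanation was tested.

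Other splits of the same libraries were counted for each comparison with at least 3 libraries per tissue. For the chick at HH18, 1 of 35 splits, the real one, gave as many genes for forelimb against flank (4146, highest other 0). The same held for hindlimb against flank (4933, highest other 0), a share under 0.05 for both. Every other split mixes the 2 tissues, which widens the spread, and the numbers pair the libraries. The 8 splits that part all 4 pairs (highest other 0 in each comparison) are too few for a share under 0.05. These counts therefore do not exclude chance. For forelimb against hindlimb 2 of 35 splits gave as many as the real 820, so chance is not excluded by this count. The other split, with 900 genes, follows numbers 1 and 2 against 3 and 4. The fit with the numbers as a block gave 2149, and no splits were counted for it. The early comparisons have 10 splits each, too few for a share under 0.05: the chick counts were 987 (1 split as large, highest other 0), 1697 (1, highest other 0) and 1927 (1, highest other 86), and the emu somatopleure count was 0 in all 10 splits. For the species difference of somatopleure against lateral plate 6 of 100 drawn splits gave as many as the real 273, with 688 the highest other. By the share set beforehand (0.05), chance is not excluded. All 5 others are among the 8 drawn splits besides the real one that keep the chick tissues and regroup the emu libraries alone. The count is therefore reached without the real emu grouping. The splits that regroup the chick libraries called at most 3 genes. They move the chick tissue difference into the spread, so their low counts cannot decide.

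In the 22 groups of 4 libraries tested, 3 had a library far from the others, where chance gives about 1 in 20. The gene9452 stood at 14.1 CPM in chick forelimb 3 (others 11.4 to 11.8), gene19928 at 0.136 in chick forelimb 3 (2 counts, others 0) and gene13598 at 320.4 in chick flank 1 (others 3.74 to 30.3). For gene19928 the rule could not have come out otherwise, since any count beside libraries at 0 is flagged. The chick HH18 entry with no identifier, used in no comparison, held up to 0.305% of a library.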

How the results depend on the processing

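The tests on numbered subsets, with a term for numbers 1 and 2 against 3 and 4, and of the lists and the between-species correlation with libraries left out, were chosen only after the results were seen. DESeq2's size factors in edgeR kept each gene count within 1.5 times and moved no direction. Where a count moved, the cause was not tested beyond the smaller or larger number of libraries, genes or terms each setting has by construction.

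With the library number as a block, chick HH18 counts were 7709 (forelimb against flank), 8205 (hindlimb against flank) and 2149 (forelimb against hindlimb), and they held all 4146, 4933 and 820 genes of the fit without it. Emu counts were 41, 2915 and 2188. The block changed no call of a named HH18 gene. In the same order, only chick numbers 1 and 2 gave 1949, 2897 and 151, 1 and 3 gave 652, 1257 and 40, 1 and 4 gave 1375, 2151 and 63, 2 and 3 gave 926, 1493 and 108, and 2 and 4 gave 924, 1422 and 85. With a term for numbers 1 and 2 against 3 and 4, forelimb against hindlimb gave 1241. DESeq2 called 154, 2561 and 2038 genes in the emu HH18 comparisons, 140 for emu somatopleure against lateral plate, and 594 and 831 for the species differences of somatopleure against lateral plate and against splanchnopleure. No filter gave 26 for emu forelimb against flank. Only the tissues compared gave 0 there (2 otherwise), 550 for emu forelimb against hindlimb and 562 for emu somatopleure against splanchnopleure. Without both emu libraries of another stage label, splanchnopleure against lateral plate gave 654, somatopleure against splanchnopleure 453, and the species differences of somatopleure and splanchnopleure against lateral plate 88 and 577. Over genes with a mean log2 CPM of at least 3 in both species, r was 0.467 for splanchnopleure against lateral plate and 0.544 between the layers.

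With 1 library left out, counts ranged from 3441 to 3835, 4281 to 4638 and 655 to 708 (chick HH18), 581 to 1055, 816 to 1481 and 1192 to 2164 (chick early), 0 to 2, 54 to 924 and 21 to 578 (emu HH18), 0 to 1, 353 to 1607 and 263 to 1578 (emu early), and 137 to 355, 240 to 984 and 214 to 725 (species differences). A tissue left with 1 library is taken to vary like the others. The correlation between species ranged from 0.162 to 0.267, 0.345 to 0.418 and 0.445 to 0.506. Over all such fits, calls of named genes were lost in 876 cases, gained in 19 and kept on their side in 3656, with no direction turned. Among lists, 36 calls were lost and 43 gained, and endothelium in emu somatopleure against lateral plate turned in its test without somatopleure 5 (mean -0.12, adjusted p = 0.975); its mean ranged from -0.66 to -0.12, and the cause was not tested. An estimated correlation ended all 57 list calls. Named genes' calls were lost in 5 cases and gained in 9 by DESeq2, lost in 2 with its size factors in edgeR, in 4 with no filter and in 47 with only the tissues compared (4 gained). Without both emu libraries of another stage label 124 were lost and 226 stayed on their side.

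Not run were species differences and lists at HH18, with their replicate block, since those identifiers share no names. The early numbers differ between tissues, so no block was fitted there. At these depths, in simulations edgeR recovered 30 to 65 of 100 genes changed 2-fold and 72 to 94 of 100 changed 4-fold.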

Other observations

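The tests of lists with libraries left out and the library positions were chosen only after the results were seen.

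Other lists describe what else the early tissues hold. Cell cycle genes did not pass singly in the chick somatopleure against the lateral plate (0 of 27 by edgeR, and 0 adjusted over the list alone; over all genes 2448 had an unadjusted p under 0.05, and DESeq2 called 1297), but lay higher as a list (adjusted p = 0.00786, and adjusted p = 0.276 with an estimated correlation). Against the splanchnopleure 5 of 27 were higher in the chick somatopleure (5 adjusted over the list alone, adjusted p = 0.00134, and adjusted p = 0.255 with an estimated correlation). There were 3 without somatopleure 63, 12 without splanchnopleure 50 and 2 without splanchnopleure 61 or 64. In the emu somatopleure they lay lower than in the lateral plate as a list (adjusted p = 0.0215, and adjusted p = 0.616 with an estimated correlation). None passed singly by edgeR (0 of 27, and 0 adjusted over the list alone; over all genes 1107 had an unadjusted p under 0.05, and DESeq2 called 140). The list was lost without lateral plate 8 (0.0506) or somatopleure 13 (0.305) or 5 (0.110). Against the splanchnopleure 1 of 27 was higher in the emu somatopleure (0 adjusted over the list alone, adjusted p = 0.00244, and adjusted p = 0.587 with an estimated correlation). There were 0 without somatopleure 53 or splanchnopleure 6, 4 without somatopleure 5 and 2 without splanchnopleure pool. The list was lost without splanchnopleure 6 (0.0591). Between the species the change from the lateral plate was higher in the chick somatopleure as a list (adjusted p = 2.08e-04, and adjusted p = 0.550 with an estimated correlation). Singly, 0 of 27 passed by edgeR (0 adjusted over the list alone; over all genes 1667 had an unadjusted p under 0.05, and DESeq2 called 594), and 1 was higher without emu somatopleure 53. For the splanchnopleure 2 were higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 4.53e-04, and adjusted p = 0.750 with an estimated correlation). Of the 27, 1 was higher without chick lateral plate 30, 31 or 32, chick splanchnopleure 50 or emu lateral plate 1 or 23. None was higher without emu splanchnopleure 6, 4 were without chick splanchnopleure 64 and 8 without emu splanchnopleure pool. None was lower without chick lateral plate 31, emu lateral plate 1 or emu splanchnopleure 6. In the emu splanchnopleure against the lateral plate 6 of 27 fell and 1 rose (8 and 1 adjusted over the list alone, adjusted p = 6.22e-05, and adjusted p = 0.416 with an estimated correlation). Their falls numbered 1 without lateral plate 1 or 8, 3 without lateral plate 23 and 0 without splanchnopleure 6. Among BMP pathway genes 3 of 14 rose and 1 fell in the chick somatopleure against the lateral plate (4 and 2 adjusted over the list alone, adjusted p = 0.549), where the mean (-0.20) and the direction of the test, upward, differ in sign, and none fell without lateral plate 31 or 32 or somatopleure 60 or 63. Surface ectoderm markers did not change singly in the chick somatopleure against the lateral plate (0 of 9, and 0 adjusted over the list alone, adjusted p = 0.304). Against the splanchnopleure they lay higher as a list (0 of 9 singly, and 0 adjusted over the list alone, adjusted p = 0.0389, and adjusted p = 0.542 with an estimated correlation). That call was lost without somatopleure 15 (0.136) or 63 (0.0573) or splanchnopleure 50 (0.191) or 64 (0.0826); 7 were higher without splanchnopleure 61, and 1 was lower without splanchnopleure 50. In the chick splanchnopleure against the lateral plate 1 of 9 rose (1 adjusted over the list alone, adjusted p = 0.127) and none without lateral plate 30, while 5 fell and the list passed without splanchnopleure 61 (1.37e-04). In the emu splanchnopleure against the lateral plate 4 of 9 fell (5 adjusted over the list alone, adjusted p = 8.10e-04, and adjusted p = 0.416 with an estimated correlation), such as TFAP2C (-3.25) and WNT6 (-3.48), and 2 fell without splanchnopleure 6. Between the species these splanchnopleure changes did not differ in the list (0 of 9 called by edgeR, 2 higher adjusted over the list alone, adjusted p = 0.439), with 1 higher in the chick without chick splanchnopleure 50 or 64 or emu splanchnopleure pool.

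Epithelial junction and basement membrane genes fell in 4 of 14 cases in the chick somatopleure against the splanchnopleure (7 adjusted over the list alone, adjusted p = 0.0217, and adjusted p = 0.290 with an estimated correlation), among them CLDN5 (-2.60) and CLDN3 (-2.01). The list call was lost without somatopleure 15 (0.111) or splanchnopleure 61 (0.0645). Cardiac muscle genes fell in 4 of 9 cases in the chick somatopleure against the lateral plate (5 lower and 1 higher adjusted over the list alone, adjusted p = 0.0125, and adjusted p = 0.276 with an estimated correlation). They numbered 1 without lateral plate 31 or somatopleure 63 and 2 without lateral plate 30 or 32 or somatopleure 15 or 60, and the list was lost without somatopleure 63 (0.0621). The species difference there was lower in the chick in 2 of 8 (4 lower and 1 higher adjusted over the list alone, adjusted p = 0.0368, and adjusted p = 0.290 with an estimated correlation). It was lost without chick somatopleure 63 (0.0676) or emu somatopleure 53 (0.116). The lower genes numbered 0 without chick lateral plate 30, chick somatopleure 63 or emu lateral plate 8, and 1 without chick lateral plate 31, chick somatopleure 60 or emu somatopleure 13 or 53; 1 was higher without chick lateral plate 31. In the emu splanchnopleure against the lateral plate 3 of 10 rose (3 adjusted over the list alone, adjusted p = 0.0430, and adjusted p = 0.376 with an estimated correlation), 1 without lateral plate 1, 23 or 8 and 0 without splanchnopleure 6. Without splanchnopleure pool 2 rose and the list was lost (0.126). There, 1 of 8 endoderm genes rose (1 adjusted over the list alone, adjusted p = 0.0112, and adjusted p = 0.376 with an estimated correlation), and 2 did without lateral plate 23 or 8. That list was lost without splanchnopleure pool (0.0623). Nephric and intermediate mesoderm markers had 2 falls among 5 in the chick somatopleure against the lateral plate (2 adjusted over the list alone, adjusted p = 0.0900), with 1 fall without any library but somatopleure 15, and the list passed without lateral plate 30 (0.0351) or somatopleure 15 (0.0300). There, neural crest markers had 0 changes among 4 (0 adjusted over the list alone, adjusted p = 0.283). Neural tube markers were tested in the emu only, with 2 of 4 higher and 1 lower in the splanchnopleure against the lateral plate (3 and 1 adjusted over the list alone, adjusted p = 0.212), and 1 higher without splanchnopleure 6.

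Over the genes that rose in the chick somatopleure, the median log2 difference from the lateral plate mean was 0.89, 0.90 and 1.08 in chick somatopleure 15, 60 and 63. In the emu (337 genes) the median was 0.15 in somatopleure 13, 0.04 in 53 and 0.27 in 5. In the splanchnopleure libraries it was 0.40 to 0.52 in the chick, and 0.15 and 0.22 in the emu. Over the genes that fell in the chick somatopleure, picked alike, it was -1.24 to -1.16 there and -0.21 to -0.15 in the chick splanchnopleure. In the emu the 610 of these measured stood at -0.15 in somatopleure 13, -0.07 in 53 and -0.22 in 5, and at 0.47 and 0.30 in splanchnopleure 6 and pool.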
